A study of Mus musculus with 24 samples.

How the data were processed

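RNA was measured in 24 libraries of sorted mouse liver cells, 3 for each of 8 groups formed by genotype (wt or ko) and sorted fraction (macrophages and 3 LSEC gates on CD117). The deposited files hold 1 library each, and their values are raw read counts per gene, which the authors made with STAR and featureCounts on mm10; the versions and settings are not stated in the labels. All values were whole numbers whose totals differed between libraries, and no normalization by the authors was found. The files list 41585 genes under RefSeq-type symbols, 27 of which are date-like names produced by a spreadsheet program; these stayed in the tests and are not named. Of 41583 distinct symbols, 37085 were found in a RefSeq annotation of mm10, from which gene positions were taken. Total counts were 2022971 to 55312465 per library. The 2 shallow libraries, wt LSEC Mid replicates 1 and 3, held 3218487 and 2022971.

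Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0, and figures were drawn with matplotlib 3.10.9. Genes were filtered by filterByExpr on the groups with a minimum count of 10, libraries were scaled by TMM, and groups were compared by the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over the genes of each comparison, at an adjusted p under 0.05. Endothelial comparisons used 18 libraries in 6 groups (12 residual degrees of freedom), the macrophage comparison used 6 libraries (4), and comparisons of both cell types used all 24 (16). The comparisons were Hi against Lo, Mid against Lo and Hi against Mid in wt, Hi against Lo in ko, the interaction of gate and genotype, ko against wt in each gate and averaged over the gates, ko against wt in macrophages, the difference of the genotype effect between macrophages and endothelium, and wt macrophages against the wt gates. Hi against Lo averaged over both genotypes was added after the data were seen. Levels are CPM with SD, that is, counts scaled to the library total multiplied by its TMM factor. Standard errors of fold changes come from the edgeR fit and are not given for genes with a group at 0. Myd88 and Kit were also tested within fractions by two-sided exact permutation tests of log2 CPM with a pseudocount of 1 CPM.

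Before the data were examined, 37 gene lists with 547 genes were fixed, covering lobule position, vessel type, signalling pathways, cell state and markers of other cell types that a sort could carry. A list was tested where at least 3 members passed the filter, and 35 were tested in each comparison. The list of mitochondrial genome genes had 0 members in the files under those symbols and is not analysed here, and the sex list was read per library. The test was camera on voom values with a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. Adjusted p values over the members of a list alone were computed from the edgeR p values.

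Named genes were chosen by a rule fixed before the data were examined: Myd88 and Kit in every comparison, and up to 10 genes per direction with the largest change among those past the threshold, with at least 5 CPM in the higher group, no overlap between the replicates compared, and a symbol that is neither a predicted or clone-based name nor an antigen receptor segment. List members named as examples were taken by smallest p. A planned test of called genes within 10 Mb of Myd88 was set to run only for a ko against wt comparison with at least 5 calls. None of the 5 such comparisons had that many, the most being 4, so neither it nor its other windows were run.

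The whole procedure was tested on simulated data with the depth and spread of these libraries, in which 100 genes were changed 2-fold and 100 changed 4-fold. The changed genes were drawn from those with a mean of at least 5 CPM and outside the lists, so recovery of genes at lower levels was not tested. The interferon-stimulated list was raised 2-fold as well. For wt Hi against Lo it recovered 14 and 75 of them with 5 false calls, for ko against wt averaged over the gates 79 and 97 with 13, for Hi against Lo averaged over genotypes 54 and 92 with 10, for macrophages 14 and 77 with 7, and for wt macrophages against endothelium 34 and 87 with 5. The simulated libraries were independent, which those of the gates are not if they share livers.

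The alternatives chosen before the data were examined were DESeq2's size factors within edgeR, no filter beyond a count above 0, a filter of at least 1 CPM in at least 3 libraries, DESeq2's Wald test, limma-voom with sample quality weights, only the groups compared (for macrophages, all 24 libraries), and leaving out each library in turn. Added after the data were seen were a robust quasi-likelihood fit, leaving out the 4 wt libraries with Y-linked transcripts (more than 5 CPM summed), leaving out the 2 shallow libraries, and, for gate comparisons only, 4 surrogate variables estimated either from scaled counts or from CPM. A 95% interval for counts was not needed, as no share of a single library is reported.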

Results

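Poly(A)-selected, stranded RNA libraries were sequenced from cells sorted out of mouse liver, in 24 libraries that fall into 8 groups of 3. Mice carried either wild-type Myd88 alleles (wt) or floxed Myd88 alleles (ko) together with iCad5, read here as an inducible Cre line driven by the endothelial cadherin gene Cdh5. The labels do not state whether wt mice carried the Cre, so ko against wt is not separated here from the Cre or its induction. Myd88 is the adaptor through which most Toll-like receptors and the interleukin-1 receptor family signal. From each genotype 4 fractions were sorted: macrophages, and liver sinusoidal endothelial cells (LSEC) gated as high, middle or low for CD117 (Hi, Mid and Lo), the receptor tyrosine kinase encoded by Kit. Total counts ran from 2022971 to 55312465 per library. Wt LSEC Mid replicate 1 held 3218487 counts and wt LSEC Mid replicate 3 held 2022971, and the other libraries held at least 21561459. Levels are given as CPM, which are counts scaled to the library total multiplied by its TMM factor. Within groups, the lowest Pearson correlation of log2 CPM between libraries was 0.874, taken across genes, which are not independent replicates. Replicate numbers follow the order of deposition and were not used to match libraries. In each of the 4 fractions, wt replicate 2 carried Y-linked transcripts, at 77.4 to 113 CPM summed, and the other wt and all ko libraries carried at most 0.0634 CPM, so sex and genotype overlap in part.

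The sorted fractions were compared first, to see whether they carried the markers of their names. Macrophage libraries held the transcripts of Kupffer cells, the resident macrophages of the liver, and endothelial libraries held those of sinusoidal endothelium. The Kupffer cell receptor Clec4f was at 17470 ± 3520 CPM (SD, n = 3) in wt macrophages and at 100 ± 32.5 to 268 ± 48.5 CPM in the wt endothelial gates. Stab2, a scavenger receptor of sinusoidal endothelium, was at 554 ± 294 CPM in wt macrophages and at 3643 ± 1217 to 3990 ± 1343 CPM in the wt gates. Of 15 sinusoidal markers 14 were lower in macrophages over all genes and 15 adjusted over the list alone, all 14 general endothelial markers were lower by both, and 18 of 19 Kupffer markers were higher by both. The remaining Kupffer marker, the transcription regulator Id3, had a log2 fold change of -0.83 (SE 0.39, adjusted p = 0.105). Genes named by the rule as higher in macrophages included Mmp27, a matrix metalloproteinase, at 40.4 ± 5.95 CPM against 0.249 ± 0.367 CPM (SD, 3 and 9 libraries), and Il10, an anti-inflammatory cytokine, at 8.09 ± 4.43 against 0.0988 ± 0.204 CPM. Genes named as higher in endothelium included Inhbb, which encodes an activin subunit, at 161 ± 133 against 3.79 ± 2.95 CPM, and Cdh4, a cadherin, at 50.9 ± 23.0 against 1.51 ± 2.10 CPM.

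In that comparison of wt macrophages with the mean of the 3 wt gates, 6720 of 17750 genes passed, 3673 higher and 3047 lower in macrophages. By camera with its preset correlation 17 of 35 lists were called. Kupffer markers (adjusted p = 2.17e-12), Toll-like and interleukin-1 receptor signalling genes (0.000887), chemokines (0.00238) and interferon-stimulated genes (0.000388) were higher in macrophages. Sinusoidal markers (2.55e-12), general endothelial markers (3.07e-12) and flow-responsive genes (0.000632) were lower. No list call held with an estimated correlation, the adjusted p values being 0.239, 0.249, 0.357, 0.322, 0.226, 0.226 and 0.226 in that order, while fry called 22 lists. Within the signalling list 14 members were higher and 3 lower over all genes, and 16 and 4 adjusted over the list alone. These included Cd14, the lipopolysaccharide co-receptor (log2 fold change 5.52, SE 0.39), and the kinase Irak4 (1.48, SE 0.13). Wt macrophage replicate 2 held the most endothelial RNA, with general endothelial markers at 4229 CPM summed against a range of 1513 to 4229 CPM for wt and 1541 to 2410 CPM for ko macrophages.

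The targeted gene was examined in each fraction. Myd88 transcripts were lower in ko than in wt cells of every endothelial gate and at similar levels in macrophages of both genotypes. Mean Myd88 was 21.4 ± 3.40 against 47.5 ± 2.38 CPM in the Hi gate (SD, n = 3 each), 17.4 ± 1.32 against 51.7 ± 6.62 CPM in the Mid gate and 18.4 ± 3.72 against 48.4 ± 4.90 CPM in the Lo gate. Ko gates therefore retained 45.0%, 33.7% and 38.1% of the wt level. In macrophages Myd88 was at 154 ± 16.0 CPM in ko and 150 ± 35.6 CPM in wt. All 3 ko libraries lay below all 3 wt libraries in each gate, which gave an exact permutation p of 0.1 (two-sided), the smallest that 3 against 3 libraries allow. The exact p in macrophages was 0.9. By edgeR the log2 fold change was -1.60 (SE 0.20, adjusted p = 0.00581) in Mid, -1.40 (SE 0.20, adjusted p = 0.0292) in Lo and -1.17 (SE 0.19, adjusted p = 0.242) in Hi, the last short of the threshold. The unadjusted edgeR p in Hi was 1.42e-05. In Hi Myd88 passed with DESeq2 (5.97e-05) and limma-voom with quality weights (0.0122). It did not pass there with DESeq2 size factors (0.259), the CPM filter (0.166), no filter (0.473) or the robust fit (0.255). Myd88 lies on chromosome 9 at positions 119335934 to 119340018 of mm10. Its counts cover all exons of the gene, so transcripts that lack only the floxed part are still counted.

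**Figure D1:**
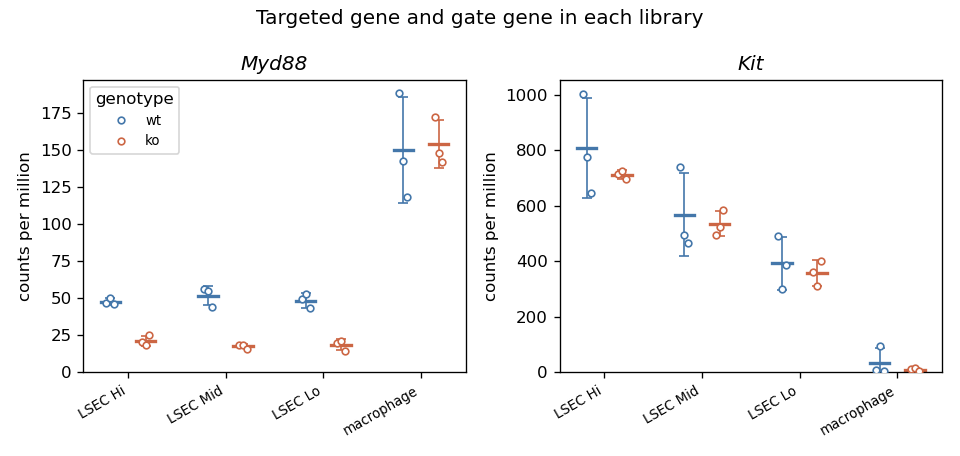
CPM of Myd88 and Kit in each library (open circles), with the group mean (bar) and SD (whisker, n = 3), for wt and ko in the 4 sorted fractions. Ko endothelial libraries lie between 14.2 and 25.1 CPM for Myd88, below all wt endothelial libraries, and Kit falls from the Hi to the Lo gate in both genotypes.

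Kit served as a check of the gates and is no finding between them. Wt Kit was at 808 ± 181 CPM in Hi, 568 ± 151 CPM in Mid and 392 ± 96.0 CPM in Lo (SD, n = 3), and ko Kit was at 711 ± 16.2, 534 ± 45.0 and 357 ± 45.8 CPM. Hi exceeded Lo in every pair of libraries in both genotypes (exact permutation p = 0.1, two-sided, the smallest possible).

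The series describes the gates as a gradient of endothelial cells across the liver lobule, and the wt Hi and Lo gates were compared to see what differed along it. In wt cells 3 genes passed. Sdc1, which encodes the heparan sulfate proteoglycan syndecan-1, was at 6.60 ± 4.79 CPM in Hi and 57.9 ± 18.8 CPM in Lo (SD, n = 3). Igfbp5, a binding protein of insulin-like growth factors, was at 4.52 ± 0.944 CPM in Hi and 58.3 ± 40.9 CPM in Lo. Cgnl1, a cell junction protein, was higher in Hi, at 98.4 ± 10.1 against 37.2 ± 3.12 CPM. The log2 fold changes were -3.12 (SE 0.43, adjusted p = 0.0168), -3.68 (SE 0.52, adjusted p = 0.0168) and 1.41 (SE 0.22, adjusted p = 0.0374). Sdc1 lies on chromosome 12 at 8771396 to 8793716, Igfbp5 on chromosome 1 at 72858065 to 72874865 and Cgnl1 on chromosome 9 at 71626507 to 71809300. The test covered 16984 genes, of which 257 had an unadjusted p under 0.05. Leaving out wt Hi replicate 2, wt Hi replicate 3 or wt Lo replicate 2 gave 0 calls and leaving out wt Lo replicate 3 gave 1. Sdc1 stayed past the threshold without wt Hi replicate 1, wt Lo replicate 1 or wt Lo replicate 3 (adjusted p = 0.000329, 0.0183 and 0.0431). Igfbp5 stayed only without wt Lo replicate 1 (0.00207). The Cgnl1 call was lost in all 6 fits that left out 1 library (0.0964 to 0.368) and with DESeq2 size factors (0.0534). Fitting only the 6 libraries compared gave 0, with log2 fold changes of -3.12 for Sdc1, -3.68 for Igfbp5 and 1.41 for Cgnl1. Leaving out the 3 wt endothelial libraries with Y-linked transcripts gave 0, with -2.52, -3.61 and 1.33 in that order. DESeq2 called 18 genes and limma-voom with quality weights 54, each with these 3 among them.

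**Figure D2:**
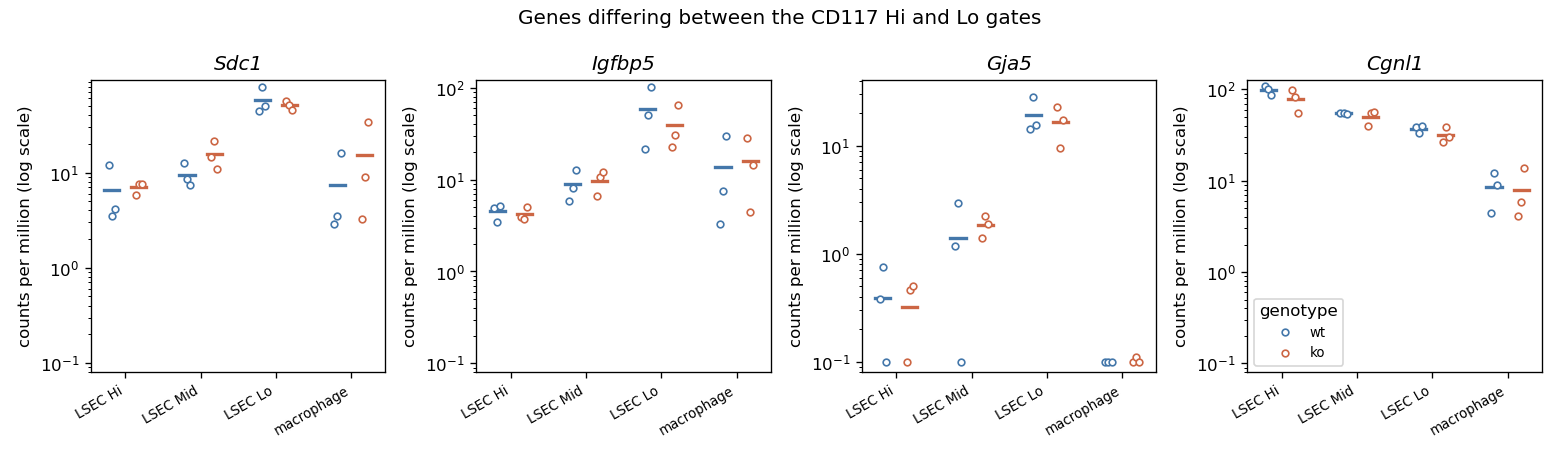
CPM on a log scale for Sdc1, Igfbp5, Gja5 and Cgnl1 in each library (open circles) with group means (bars), for wt and ko in the 4 sorted fractions, n = 3 per group. Values under 0.1 CPM are drawn at 0.1. Sdc1, Igfbp5 and Gja5 are highest in the Lo gate and Cgnl1 in the Hi gate, in both genotypes.

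Marker lists of lobule position and vessel type were also compared between the wt Hi and Lo gates. All 10 periportal LSEC markers were lower in Hi (camera adjusted p = 2.19e-16, and 0.00995 with an estimated correlation), with a median log2 fold change of -0.80. They included Dll4 and Jag1, ligands of Notch receptors (-0.87, SE 0.22, and -1.70, SE 0.46), and the ephrin Efna1 (-0.74, SE 0.20). Markers of arterial endothelium fell, 9 of 11 members being below 0 (1.45e-11, and 0.00125 with an estimated correlation), among them Gja5, the gap junction protein connexin 40 (-5.59, SE 0.997), and Hey1, a Notch target (-1.84, SE 0.63). The summed level of the arterial list, set by its most abundant members, was similar in both gates, at 2006 ± 485 CPM in Hi and 2111 ± 440 CPM in Lo (SD, n = 3). Markers of continuous or large-vessel endothelium fell as well, with 9 of 11 below 0 (1.28e-13, and 0.0016 with an estimated correlation), among them Ly6c1 (-3.55, SE 0.79) and Vwf, von Willebrand factor (-2.23, SE 0.73). The Notch pathway list fell, with 8 of 13 members below 0 (8.33e-05, and 0.0492 with an estimated correlation), and it shares Dll4, Jag1 and Hey1 with the lists above. Adjusted over the list alone, 4 periportal, 3 arterial, 5 large-vessel and 3 Notch members were lower. None of these named members passed over all genes. All 4 lists were called in all 6 fits that left out 1 library.

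All 10 pericentral LSEC markers were above 0 in wt Hi cells (camera adjusted p = 6.58e-09, and adjusted p = 0.0571 with an estimated correlation), with a median log2 fold change of 0.60. Values included Rspo3, an enhancer of Wnt signalling (2.26, SE 0.75), Wnt9b, a Wnt ligand (1.51, SE 0.74), and Cdh13 (1.01, SE 0.39), and 0 members passed when adjusted over the list alone. Transcripts of other cell types also differed between the gates with the preset correlation. Stellate cell markers summed to 818 ± 161 CPM in wt Hi and 391 ± 52.6 CPM in wt Lo (SD, n = 3; camera adjusted p = 1.28e-13, and 0.0707 with an estimated correlation). Kupffer markers summed to 2599 ± 404 and 1763 ± 431 CPM (4.65e-07, and 0.592). Hepatocyte markers summed to 3510 ± 1556 in Hi and 6140 ± 5162 CPM in Lo (0.000813, and 0.71), a call lost without wt Hi replicate 2 (adjusted p up to 0.896 over the 6 fits) or wt Lo replicate 3. T and NK cell markers summed to 23.8 ± 1.94 and 38.3 ± 16.7 CPM (0.000511, and 0.592), a call lost without wt Lo replicate 3 (0.101). In all, 14 of 35 lists were called, 4 of them with an estimated correlation and 2 by fry.

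The adjacent gates were compared in wt cells to see where along the gradient the levels changed. No gene passed between Mid and Lo or between Hi and Mid by edgeR, with 274 and 150 genes at an unadjusted p under 0.05. DESeq2 called 7 and 1, and limma-voom with quality weights 0 and 0. Between Mid and Lo, Sdc1 had a log2 fold change of -2.60 (SE 0.43, adjusted p = 0.24). Between Hi and Mid it had -0.52 (SE 0.42). The Mid mean lay between the Hi and Lo means for 11 of 12 genes in each genotype, the 12 being the genes other than Kit called between Hi and Lo with both genotypes averaged, a set chosen on the same libraries. Between Mid and Lo, arterial markers (10 of 11 below 0, camera adjusted p = 1.17e-08, and 0.00507 with an estimated correlation) and large-vessel markers (9 of 11 below 0, 1.17e-08, and 0.00952) were lower in Mid. Periportal markers were below 0 in 10 of 10 (1.15e-07, and adjusted p = 0.156 with an estimated correlation). Between Hi and Mid, pericentral markers were above 0 in 10 of 10 (0.000597, and adjusted p = 0.937 with an estimated correlation), a call lost without wt Hi replicate 1 or wt Mid replicate 2 (up to 0.0912). Stellate cell (2.88e-09, and 0.937) and Kupffer markers (0.000277, and 0.937) were higher in Hi than in Mid, calls lost without wt Mid replicate 2. Hepatocyte (0.00315, and 0.713), T and NK cell (0.0384, and 0.713), B and plasma cell (0.0197, and 0.552) and monocyte markers (0.023, and 0.713) were lower in Mid than in Lo, with calls lost in 2, 3, 3 and 2 of 6 fits that left out 1 library. The Mid group has the 2 shallow libraries.

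The gates of ko mice were compared in the same way. No gene passed by edgeR between ko Hi and ko Lo, with 507 at an unadjusted p under 0.05, while DESeq2 called 20 and limma-voom with quality weights 0. The 3 genes called in wt had log2 fold changes of -2.87 for Sdc1 (SE 0.42, adjusted p = 0.0582), -3.24 for Igfbp5 (adjusted p = 0.068) and 1.30 for Cgnl1 (adjusted p = 0.103). Leaving out ko Hi replicate 3 gave 2 calls. Arterial markers fell in ko Hi by camera (8 of 11 below 0, adjusted p = 1.98e-07, and 0.0106 with an estimated correlation), while their summed level was 2112 ± 379 CPM in Hi and 2048 ± 310 CPM in Lo (SD, n = 3). Large-vessel markers fell as well (9 of 11 below 0, 3.39e-07, and 0.0317), at 584 ± 166 against 1055 ± 399 CPM. Pericentral markers rose, with 10 of 10 above 0 (2.58e-10, and 0.0471 with an estimated correlation), including Cdh13 (1.23, SE 0.40) and Ptgs1, a prostaglandin synthase (0.79, SE 0.28). Adjusted over the list alone, 4 pericentral, 2 arterial and 3 large-vessel members passed. Periportal markers were below 0 in 10 of 10 (8.56e-09, and adjusted p = 0.0735 with an estimated correlation). Markers of other cell types moved in the same ko libraries. Stellate cell markers rose (8.56e-09, and adjusted p = 0.183 with an estimated correlation) in all 6 fits that left out 1 library, and Kupffer markers rose (0.000229, and 0.694), a call lost in 2 of them. T and NK cell (5.99e-06, and 0.344), B and plasma cell (0.00734, and 0.279) and neutrophil markers (0.00101, and 0.519) fell, with calls lost in 1, 2 and 2 of the fits. In all, 13 of 35 lists were called, 3 of them with an estimated correlation and 2 by fry.

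Whether the gate difference itself differed between genotypes was tested as an interaction. No gene passed by edgeR, with 171 at an unadjusted p under 0.05, and DESeq2 and limma-voom with quality weights called 0 each. No list was called by camera with either correlation or by fry. For Sdc1 the difference in log2 fold change, ko minus wt, was 0.25 (SE 0.56), and for Kit it was -0.06 (SE 0.32). On simulated changes in genes with a mean of at least 5 CPM, this test recovered 4 of 100 genes with a 2-fold and 38 of 100 with a 4-fold difference. A moderate difference was therefore mostly not detectable here. At an unadjusted p under 0.001, 18 genes differed between Hi and Lo in wt and 15 in ko, 9 of them shared with the same direction against 0.01 expected if the lists were independent. All 15 ko genes and 16 of the 18 wt genes, Kit included, had the same sign in the other genotype.

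**Figure D3:**
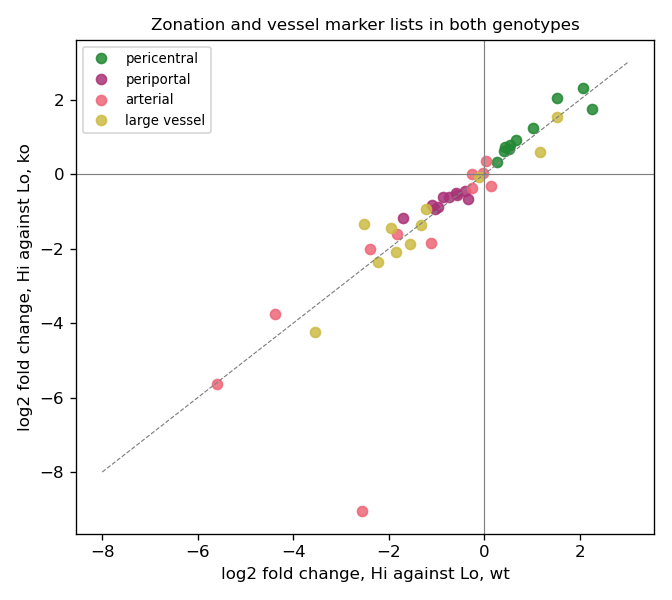
Log2 fold change of Hi against Lo in wt (horizontal) and ko (vertical) for each member of the pericentral, periportal, arterial and large-vessel marker lists, with the line of equal change dashed. All 10 pericentral members lie above 0 and all 10 periportal members below 0 on both axes. The lowest point on the vertical axis is Bmx, which had no counts in ko Hi cells, so its fitted value depends on the prior count.

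Averaging Hi against Lo over both genotypes, a comparison added after the data were seen, gave 13 genes, 3 higher and 10 lower in Hi, with 696 at an unadjusted p under 0.05. The 3 higher were Cgnl1 (log2 fold change 1.35, SE 0.16), Sema3d, a secreted semaphorin (1.44, SE 0.25), and the gate gene Kit (1.02, SE 0.16). The lower genes included Gja5 (-5.61, SE 0.71, adjusted p = 0.00199), Adgrg6, an adhesion G protein-coupled receptor (-4.85, SE 0.67), Nrg1, a ligand of ErbB receptors (-4.15, SE 0.68), and Ly6c1 (-3.90, SE 0.57). They also included Igfbp5 (-3.46, SE 0.36), Lmo7 (-3.06, SE 0.51), Sdc1 (-2.99, SE 0.30, adjusted p = 0.00031), Ehd2, a protein of caveolae (-2.26, SE 0.40), the transcription factor Mecom (-1.68, SE 0.23) and the ephrin Efnb1 (-1.17, SE 0.16). Pericentral markers rose (camera adjusted p = 2.04e-13, and 0.0161 with an estimated correlation), and periportal (6.23e-16, and 0.0112), arterial (8.91e-12, and 0.00114), large-vessel (4.7e-12, and 0.00566) and Notch (4.75e-05, and 0.035) lists fell. Adjusted over the list alone, 6 pericentral members were higher and 7 periportal, 5 arterial, 7 large-vessel and 4 Notch members were lower. Markers of other cell types moved in the same libraries. Stellate cell (3.38e-14, and adjusted p = 0.0603 with an estimated correlation) and Kupffer markers (6.09e-08, and 0.385) rose in all 12 fits that left out 1 library. T and NK cell markers (7.43e-07, and 0.293) fell in all 12. Hepatocyte (0.00122, and 0.631), neutrophil (0.00603, and 0.585) and monocyte markers (0.0106, and 0.631) fell, with calls lost in 3, 2 and 4 of those fits. Without the wt libraries with Y-linked transcripts 4 genes passed, all among the 13, fitting only the 12 libraries compared gave 7, and leaving out wt Lo replicate 2 gave 8. More genes passed, all 13 among them, with no filter (56), limma-voom (61), DESeq2 (83) and surrogate variables (195 from scaled counts and 428 from CPM).

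The effect of the Myd88 alleles on endothelial cells was tested in each gate. Apart from Myd88 itself, no gene passed in any single gate by edgeR with the filter used here. The Hi gate gave 0 genes by edgeR, with 318 at an unadjusted p under 0.05, against 1 by DESeq2 and 1 by limma-voom with quality weights, Myd88 in each. The Mid and Lo gates gave 1 each, Myd88, with 488 and 376 genes at an unadjusted p under 0.05. DESeq2 called 2 in Mid and 1 in Lo, limma-voom with quality weights 1 in each, and edgeR with no filter 2 in Hi, 1 in Mid and 3 in Lo. Leaving out any 1 library of the gate ended the Myd88 call, except without replicate 3 of wt Mid or of wt Lo. Its log2 fold change stayed between -1.54 and -1.72 in Mid, where the adjusted p reached 0.0971, and between -1.25 and -1.52 in Lo, where it reached 0.363. The call also ended when only the 6 libraries compared were fitted (log2 fold change -1.62 in Mid and -1.40 in Lo) and without the Y-linked libraries (-1.56 and -1.33), fits with fewer residual degrees of freedom.

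Averaged over the 3 gates, 4 genes passed between ko and wt endothelium, with 1347 at an unadjusted p under 0.05. Myd88 was lower (log2 fold change -1.39, SE 0.11, adjusted p = 1.38e-05). Angpt2, which encodes angiopoietin-2, a ligand of the endothelial receptor Tie2, was higher (0.97, SE 0.15, adjusted p = 0.0472), at 37.6 ± 4.70 against 19.4 ± 7.48 CPM in Hi, 53.1 ± 6.21 against 27.4 ± 5.16 CPM in Mid and 72.1 ± 7.13 against 34.6 ± 11.02 CPM in Lo (SD, n = 3), with no overlap in any gate, which each gate alone gives by chance in 10% of groupings of 3 against 3. Mup19 (-4.68, SE 0.75) and Mup15 (-4.66, SE 0.76), major urinary proteins made by hepatocytes, were lower (adjusted p = 0.0472 for each). They fell outside the naming rule, were chosen after their values were seen, and belong to a family of near-identical paralogs, so reads can be assigned to the wrong member. Angpt2 lies on chromosome 8 at 18690263 to 18741562, Mup15 on chromosome 4 at 61435787 to 61439833 and Mup19 on chromosome 4 at 61778324 to 61782355. The labels do not tie fractions to animals, and 9 against 9 libraries that share livers give p values that are too small, since they measure the spread between these samples. Without the Y-linked wt libraries the log2 fold change of Angpt2 was 1.11 (adjusted p = 0.0598), without the 2 shallow libraries, which leaves 1 wt Mid library and takes the spread from the other groups, it was 0.88 (adjusted p = 0.58). The call also ended with the CPM filter (0.0575) and the robust fit (0.0589), and it held with DESeq2 (6.38e-06), no filter (0.000733), limma-voom (0.0182) and DESeq2 size factors (0.0465). Between 1 and 4 genes passed when 1 library was left out, Myd88 each time. Angpt2 stayed past the threshold in 2 of those 18 fits, without wt Hi replicate 3 (adjusted p = 0.0134) or wt Lo replicate 2 (adjusted p = 0.0207). Its log2 fold change ran from 0.88 to 1.06 over the 18 fits, and was 0.97 with the CPM filter and with the robust fit.

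Of the 35 lists, 8 were called between ko and wt endothelium averaged over the gates with the preset correlation, and 0 with an estimated correlation or by fry. Cell cycle genes were below 0 in 22 of 22 members (camera adjusted p = 8.44e-16, and adjusted p = 0.822 with an estimated correlation), including Rrm2, a ribonucleotide reductase subunit (-1.36, SE 0.37), Mcm2 (-0.43, SE 0.18) and Mki67 (-0.997, SE 0.46). Their summed level was 403 ± 174 against 516 ± 108 CPM in Hi, 404 ± 193 against 512 ± 36.8 CPM in Mid and 350 ± 82.8 against 453 ± 60.7 CPM in Lo (SD, n = 3), and ko and wt libraries overlapped in the Hi, Mid and Lo gates. Periportal LSEC markers were above 0 in 9 of 10 (0.00225, and adjusted p = 0.826 with an estimated correlation), including Ntn4 (0.76, SE 0.20) and Efna1 (0.32, SE 0.11). Stellate cell markers were below 0 in 9 of 13 (0.000181, and 0.826), and cholesterol synthesis genes in 15 of 19 (0.0125, and 0.826). Neutrophil (0.000174, and 0.826), monocyte (0.00225, and 0.891) and T and NK cell markers (0.00501, and 0.891) were above 0 in 10 of 10, 13 of 14 and 14 of 15 members. Monocyte markers summed to 648 ± 380 against 439 ± 168 CPM in Hi, 533 ± 297 against 375 ± 202 CPM in Mid and 650 ± 349 against 398 ± 138 CPM in Lo (SD, n = 3), overlapping in each gate. Kupffer markers, not called, summed to 3620 ± 2414 against 2599 ± 404, 2646 ± 1187 against 2074 ± 609 and 2526 ± 758 against 1763 ± 431 CPM. Neutrophil markers summed to 18.2 ± 17.3 against 7.71 ± 4.42 CPM in Hi, 23.99 ± 13.9 against 9.37 ± 5.31 CPM in Mid and 51.6 ± 38.3 against 14.7 ± 4.27 CPM in Lo, overlapping in each gate. Periportal hepatocyte markers were above 0 in 9 of 9 (0.0394, and 0.891). The cholesterol call was lost without wt Hi replicate 1, ko Hi replicate 2 or ko Lo replicate 1 (up to 0.102), the T and NK cell call without ko Hi replicate 3 (0.164) and the periportal hepatocyte call without wt Hi replicate 2, ko Hi replicate 1 or 2, wt Mid replicate 2, ko Mid replicate 2, wt Lo replicate 1 or ko Lo replicate 2 (up to 0.388). Nuclear factor kappa B targets (adjusted p = 0.317), Toll-like and interleukin-1 receptor signalling genes (0.0793), chemokines (0.659), leukocyte adhesion genes (0.659) and interferon-stimulated genes (0.304) were not called.

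Macrophages of the 2 genotypes were compared to see what differed in cells that kept their Myd88 transcripts. No gene passed by edgeR, with 315 of 15159 at an unadjusted p under 0.05, while DESeq2 called 5 and limma-voom with quality weights 0. With the preset correlation 9 of 35 lists were called, and with an estimated correlation or by fry 0. Monocyte-derived macrophage markers were above 0 in 14 of 14 (camera adjusted p = 2.51e-06, and adjusted p = 0.785 with an estimated correlation), including Chil3, a chitinase-like protein (6.26, SE 1.73), Spp1, osteopontin (5.30, SE 1.58), and S100a4 (3.71, SE 1.29). They summed to 14140 ± 2779 CPM in ko and 9840 ± 4392 CPM in wt (SD, n = 3). Spp1 is also in the cholangiocyte list, whose 3 tested members were above 0 (0.0382, and 0.785), a call lost in 4 of 6 fits that left out 1 library. Cholangiocyte markers summed to 314 ± 460 CPM in ko, with 1 library at 843 CPM, and to 11.5 ± 3.57 CPM in wt. B and plasma cell markers were above 0 in 8 of 9 (0.02, and 0.785), at 75.0 ± 10.1 against 43.7 ± 7.22 CPM with no overlap, a call lost in 3 of the 6 fits. Nuclear factor kappa B targets were above 0 in 21 of 29 (9.01e-06, and 0.785), including Nfkbiz (0.95, SE 0.22) and the acute phase gene Saa3 (4.13, SE 1.20). The summed level of these targets was similar, at 4284 ± 241 CPM in ko and 4231 ± 1044 CPM in wt (SD, n = 3), and the highest library was wt (5184 CPM). Cholesterol synthesis genes were below 0 in 18 of 19 (0.000542, and 0.785), including Fdps (-0.80, SE 0.43), a call lost without wt macrophage replicate 1 (0.276). Over these 3 lists, 0 members passed over all genes or when adjusted over the list alone.

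The genotype effect in macrophages was set against that in endothelium in 1 fit of all 24 libraries. No gene passed by edgeR, with 611 at an unadjusted p under 0.05, while DESeq2 called 7 and limma-voom with quality weights 1. For Myd88 the log2 effect in macrophages minus the mean effect in the gates was 1.43 (SE 0.23, adjusted p = 0.0777). It passed with DESeq2 (1.37e-06), with limma-voom (0.00611), with DESeq2 size factors (0.0342) and with a filter on CPM (0.0343), and without ko Hi replicate 3 (0.0459) or wt macrophage replicate 1 (0.0132). Leaving out wt macrophage replicate 1 or replicate 2 gave 5 genes each and replicate 3 gave 2.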

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

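The test of macrophage RNA in this part was chosen after the Myd88 levels were seen. The results here were picked by a test of the difference in genotype effect between macrophages and endothelium. No gene passed that test over all genes, and 2 lists were called with the preset correlation. All 40 splits of the same libraries, the real one included, called at least 2 lists, with a median of 13 in the others. Chance is therefore not excluded for these 2 lists.

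Myd88 differed between the cell types, with a log2 genotype effect in macrophages minus that in endothelium of 1.43. The unadjusted edgeR p was 4.38e-06, given because the targeted gene was singled out beforehand. The fit takes the 24 libraries as independent, so this p is not exact, and may be too small or too large, if fractions share livers. The edgeR adjusted p over all genes was 0.0777, and it ranged from 1.37e-06 to 0.369 over the alternatives. Ko endothelial libraries still held Myd88 at 14.2 to 25.1 CPM. RNA from macrophages in these libraries was tested as the source of the remaining transcripts, by taking the share of Kupffer markers in each ko endothelial library relative to macrophages and multiplying it by the Myd88 level of macrophages. This accounted for a median of 22.3% of the Myd88 counts over the 9 libraries, with a range of 13.3% to 40.5%, so macrophage RNA may supply part of the remainder, and the value argues against it as the whole of it. The Kupffer list includes Id3, which was not higher in macrophages, so the share may be too high. Clec4f alone ran from 18.9 to 859 CPM in ko endothelial libraries, against 17140 ± 2544 CPM in ko macrophages (SD, n = 3). Transcripts that lack only the floxed part, cells that did not delete the gene and other Myd88-expressing cells stay open and were not tested, because the counts are summed over the gene and the gates hold mixed cells.

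Nuclear factor kappa B targets had a higher genotype effect in macrophages than in endothelium (camera adjusted p = 0.0206, and adjusted p = 0.888 with an estimated correlation). The call was lost without each of wt Hi replicate 1, ko Hi replicate 1, wt Mid replicate 2, ko Mid replicate 1, ko Lo replicate 1, wt macrophage replicates 2 and 3 and ko macrophage replicates 2 and 3, with adjusted p values up to 0.283. The median difference in log2 fold change was 0.11, with 16 of 31 members above 0.

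Cell cycle genes also had a higher genotype effect in macrophages than in endothelium (camera adjusted p = 1.05e-05, and adjusted p = 0.888 with an estimated correlation). The call was lost without wt macrophage replicate 1 (0.0712). The median difference was 0.06, with 13 of 22 members above 0, and the list was below 0 in both cell types when each was tested alone.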

How the results depend on the processing

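No paired analysis was run because the labels number the libraries without tying the fractions to animals. Y-linked transcripts in wt replicate 2 of each fraction point to a shared liver there. Erythroid markers, picked after the values were seen, also followed the wt replicate number. They summed to 228 to 291 CPM in the gates of wt replicate 1, 768 to 1229 CPM in replicate 2 and 16.3 to 19.3 CPM in replicate 3. The unpaired tests and splits leave such sharing out. If fractions share livers, unpaired p values between fractions can be too large, so a lack of calls between gates is weak evidence of no difference. The robust fit, the fits without the Y-linked or the shallow libraries, the surrogate variables and every setting of Hi against Lo averaged over genotypes were chosen after seeing the data. Surrogate variables were run for gate comparisons only, and the tests of genes near Myd88 with windows of 10 Mb or other sizes were not run. Unless stated, the cause of a difference between settings was not tested. The depth of the 2 shallow libraries limits the Mid gate. Fits without them keep 1 wt Mid library, with the spread taken from the other groups, and a lost call there tests little. In Mid the log2 fold change of Myd88 was -1.67 without them against -1.60 with them. Also, fits of 3 against 3 libraries have 4 residual degrees of freedom.

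Counts of genes that moved past 1.5 times the reported count are given by setting. For wt Hi against Lo (3 genes), no filter gave 14, DESeq2 18, limma-voom 54, only the groups compared 0, surrogate variables 27 from scaled counts and 110 from CPM, the fit without Y-linked libraries 0, and leaving out 1 library 0 to 2. For wt Mid against Lo (0), no filter gave 5, DESeq2 7 and surrogate variables from CPM 13. For wt Hi against Mid (0), DESeq2 gave 1. For ko Hi against Lo (0), no filter gave 12, the robust fit 1, DESeq2 20, only the groups compared 1, surrogate variables 22 and 70, and leaving out 1 library 0 to 2. For the interaction (0), no filter gave 2. For ko against wt in Hi (0), no filter gave 2, DESeq2 1 and limma-voom 1. In Mid (1), DESeq2 gave 2, and only the groups compared, the fit without Y-linked libraries and the fit without shallow libraries gave 0, and leaving out 1 library gave 0 to 1. In Lo (1), no filter gave 3, only the groups compared and the fit without Y-linked libraries 0, and leaving out 1 library 0 to 1. Averaged over the gates (4), no filter gave 79, the CPM filter 1, the robust fit 1, DESeq2 87, limma-voom 11, the fit without shallow libraries 1, and leaving out 1 library 1 to 4. In macrophages (0), DESeq2 gave 5. For the difference between cell types (0), DESeq2 size factors gave 1, the CPM filter 1, DESeq2 7, limma-voom 1, and leaving out 1 library 0 to 5. For Hi against Lo averaged over genotypes (13), no filter gave 56, DESeq2 83, limma-voom 61, only the groups compared 7, surrogate variables 195 and 428, the fit without Y-linked libraries 4, and leaving out 1 library 8 to 14. Wt macrophages against endothelium (6720) stayed between 5216 and 7469 in all settings run, and between 5466 and 6738 when 1 library was left out.

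Counts of lists called by camera with the preset correlation, with an estimated correlation and by fry were 14, 4 and 2 for wt Hi against Lo (10 to 20 when 1 library was left out), 18, 2 and 0 for wt Mid against Lo (4 to 15), 5, 0 and 0 for wt Hi against Mid (2 to 7), 13, 3 and 2 for ko Hi against Lo (10 to 18), and 0, 0 and 0 for the interaction (0 to 9). They were 7, 0 and 0 for ko against wt in Hi (1 to 14), 1, 0 and 0 in Mid (0 to 11), 6, 0 and 0 in Lo (5 to 14), 8, 0 and 0 averaged over the gates (7 to 12), 9, 0 and 0 in macrophages (9 to 16), 2, 0 and 0 for the difference between cell types (1 to 9), 17, 0 and 22 for wt macrophages against endothelium (16 to 19) and 17, 5 and 5 for Hi against Lo averaged over genotypes (14 to 19).

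Directions reversed for genes that were not called and for 6 list calls. The log2 fold change of Myd88 between wt Hi and Lo (-0.020) became 0.012 with surrogate variables from CPM and 0.0017 without Y-linked libraries, and ran from -0.11 to 0.060 when 1 library was left out. Myd88 in macrophages (0.045) became -0.0093 without Y-linked libraries and ran from -0.074 to 0.25. Kit in the interaction (-0.064) became 0.070 without Y-linked libraries and ran from -0.26 to 0.15. Kit between ko and wt in Mid became 0.093 without shallow libraries and ran from -0.26 to 0.096, and in Lo it became 0.036 with limma-voom and ran from -0.31 to 0.063. Kit in macrophages (-1.79) became 0.80 without Y-linked libraries, since wt macrophage replicate 2 alone carries Kit at 93.4 CPM, and ran from -2.32 to 0.80. The difference in Kit between cell types (-1.69) became 1.05 without Y-linked libraries and ran from -2.21 to 0.96. In the interaction Sdc1 (0.25) became -0.35 without Y-linked libraries and ran from -0.046 to 1.06, Igfbp5 (0.44) ran from -0.21 to 1.01 (negative without wt Lo replicate 3), and Cgnl1 (-0.12) ran from -0.30 to 0.091 (positive without ko Hi replicate 3 or ko Lo replicate 2). For those lists, adjusted p values over the fits without 1 library are given with the library that reversed the direction. Immediate early genes in wt Mid against Lo ran from 4.29e-05 to 0.968 (wt Mid replicate 2, 0.838), and erythroid markers from 0.000512 to 0.721 (wt Mid replicate 2, 0.293, and wt Lo replicate 3, 0.721). Erythroid markers in wt Hi against Mid ran from 0.000135 to 0.853 (wt Mid replicate 2, 0.69). Kupffer markers in ko Hi against Lo ran from 4.66e-10 to 0.892 (ko Lo replicate 1, 0.698), cell cycle genes in macrophages from 1.04e-06 to 0.315 (wt macrophage replicate 3, 0.277), and hepatocyte markers in Hi against Lo averaged over genotypes from 7.13e-09 to 0.988 (ko Lo replicate 2, 0.988).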

Other observations

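The tests of the Mup genes and of immune cell markers in this part, and the comparison of Hi with Lo averaged over genotypes, were chosen after the results were seen.

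Several groups of genes fixed beforehand were not called along the CD117 gates with both genotypes averaged. Sinusoidal markers (camera adjusted p = 0.562), chemokines (0.562), leukocyte adhesion genes (0.397), heparan sulfate synthesis genes (0.906), matrix and proteoglycan genes (0.562), angiocrine factors (0.523), flow-responsive genes (0.562), nuclear factor kappa B targets (0.475) and Toll-like and interleukin-1 receptor signalling genes (0.961) were among them. Within the matrix and proteoglycan list Sdc1 was lower in Hi, while 16 members were above 0 and 14 below. The angiocrine list, which shares Rspo3 and Wnt9b with the pericentral list, had 2 members higher and 1 lower when adjusted over the list alone. Cholesterol synthesis genes were below 0 in 18 of 19 members (6.04e-05, and adjusted p = 0.269 with an estimated correlation). B and plasma cell markers were below 0 in 8 of 9 (0.00533, and 0.269), and dendritic cell markers in 8 of 9 (0.00705, and 0.438).

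In ko macrophages, Kupffer markers were above 0 in 14 of 19 (camera adjusted p = 0.0144, and adjusted p = 0.785 with an estimated correlation), with summed levels of 96650 ± 5044 CPM in ko and 88950 ± 13750 CPM in wt (SD, n = 3). Cell cycle genes were below 0 in 20 of 22 (0.0148, and 0.936), a call lost without wt macrophage replicate 3 or ko macrophage replicate 2 (up to 0.315). T and NK cell markers were above 0 in 10 of 11 (0.00561, and 0.785), a call lost without wt macrophage replicate 3 or ko macrophage replicate 3 (up to 0.222). The Kupffer call was lost without wt macrophage replicate 2 or 3 or ko macrophage replicate 1 (up to 0.255).

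Mup19 and Mup15 were lower in ko endothelial libraries, at 0 to 2.91 CPM in ko and 1.61 to 52.0 CPM in wt over the 3 gates, and Mup19 was at 0.0443 to 1.51 CPM in ko and 1.45 to 27.6 CPM in wt macrophages. The male-biased wt libraries argue against being the whole source, since the mean log2 fold change of both genes was -4.40 without the libraries that carry Y-linked transcripts, although neither call held there. Less hepatocyte RNA in ko libraries is argued against as the whole source by the hepatocyte list. Its 20 members had a median log2 fold change of 0.45, and 18 of them were above 0. Summed hepatocyte markers lay above all wt libraries of the gate only in ko replicate 2 (7835, 14600 and 28570 CPM in Hi, Mid and Lo). Ko replicates 1 and 3 held 1521 to 3698 CPM over the gates, against 1790 to 12080 CPM in wt. All 18 Mup genes tested had log2 fold changes below 0, so no member gained on average what these lost. Mup3 (-0.15, SE 0.50), at 15.6 to 238 CPM in the endothelial libraries, varies by more than the levels of Mup19 and Mup15, so reads moved to it are not ruled out. Reads shared between Mup paralogs, an allele or strain difference around the cluster on chromosome 4 and a difference between the livers stay open, because the files give counts per gene and the labels give no strain. The genotype stays open as well, and no value separates it from these.

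Neutrophil, monocyte and T and NK cell markers were higher in ko endothelial libraries averaged over the gates, each with a call that ended with an estimated correlation. A lower endothelial share in ko libraries would raise the markers of other cells alike. Stellate cell markers fell, with a median log2 fold change of -0.42, but their sums overlapped in every gate and the adjusted p was 0.826 with an estimated correlation. Hepatocyte (median 0.45), Kupffer (0.62), cholangiocyte (1.27) and B and plasma cell markers (0.54) were above 0, so a lower share stays open. For hepatocyte markers, only ko replicate 2 summed above all wt libraries of its gate. General endothelial markers summed to 24900 ± 1039 CPM in ko against 23260 ± 738 CPM in wt in Hi (SD, n = 3). They were at 24220 ± 2053 against 23650 ± 999.9 CPM in Mid and 23020 ± 2776 against 23110 ± 405 CPM in Lo. These sums were thus not lower in ko in Hi or Mid. A single library is argued against for neutrophil markers, whose largest adjusted p was 0.00359 over the 18 fits that left out 1 library, while all libraries of 1 liver could not be left out together. For neutrophil markers the lowest ko library lay above the highest wt library in 0 of 3 gates, and below the lowest wt library in Hi (2.99 against 3.52 CPM) and Lo (7.41 against 11.1 CPM), so not every ko library lay above the wt level. RNA from macrophages was estimated as the share of Kupffer markers times the list's level in macrophages of the same genotype. It would bring a median over the gates of 99.8% of the ko minus wt difference in summed monocyte markers (116% in Hi and 69.4% in Lo). That value also holds the difference between ko and wt macrophages themselves (14140 ± 2779 against 9840 ± 4392 CPM, SD, n = 3). The call of that difference ended with an estimated correlation. How much of the monocyte rise comes from carried macrophage RNA therefore stays open. Macrophage RNA would bring 12% for neutrophil and 3.32% for T and NK cell markers, at most 28.1% in any gate, which argues against it as the whole source there. The limit of the Kupffer share given for Myd88 applies to these values too. More immune cells in some ko livers, and sorting that carried more of them, may both apply and were not separated.

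The same libraries were regrouped to see how often another split gave as many genes. For the comparisons of 3 against 3 libraries only 10 splits exist, too few for a share under 0.05. Wt Hi against Lo called 3 genes and the highest other split 0 (1 of 10 as large), and ko against wt called 1 gene in Mid and 1 in Lo with 0 as the highest other (1 of 10 each). Wt Mid against Lo, wt Hi against Mid, ko Hi against Lo and ko against wt in Hi called 0, as did every other split (10 of 10), and macrophages called 0 with 1 as the highest other (10 of 10). For Hi against Lo averaged over genotypes 13 genes were called, the gate gene Kit among them, and no other of 100 drawn splits called any (1 of 100). Wt macrophages against endothelium called 6720 genes against 1235 in the highest other split (1 of 40). These shares exclude chance as the source of the counts only if the libraries are independent. The Y-linked transcripts in wt replicate 2 of each fraction leave that in doubt. For ko against wt averaged over the gates 4 genes were called, 2 of 100 splits were as large and the highest other reached 249. That share would exclude chance on the same condition. A split with that many genes points to a structure of the samples that the groups do not hold, such as libraries that come from the same liver, so chance is not treated as excluded for that count. The interaction called 0 against 2552 in the highest other split (100 of 100), and the difference of genotype effects between cell types called 0 against 77 (40 of 40), which point to such a structure as well.

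The counts of lists called with the preset correlation were matched by other splits in most comparisons. Of 100 splits, 60 called as many lists as ko against wt averaged over the gates (8, highest other 19) and 12 as many as Hi against Lo averaged over genotypes (17, highest other 27). Of 40 splits, 5 matched wt macrophages against endothelium (17, highest other 20) and 40 matched the difference of genotype effects (2, highest other 17). Chance is not excluded for any of these 4 counts. The interaction called 0 lists (highest other 19), a count that each of the 100 splits reaches, so it tests nothing. With 10 splits, too few for a share under 0.05, 2 matched wt Hi against Lo (14, highest other 16), 1 wt Mid against Lo (18, highest other 11), 8 wt Hi against Mid (5, highest other 12), 4 ko Hi against Lo (13, highest other 20), 8 ko against wt in Hi (7, highest other 14), 10 in Mid (1, highest other 13), 8 in Lo (6, highest other 17) and 8 in macrophages (9, highest other 18).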
